A study of Mus musculus with 2 samples.

How the data were processed

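MicroRNA sequencing libraries were made from adrenal glands of 2 male B6CASTF1/J mice aged 36 days, per the labels. B6CASTF1/J is the F1 hybrid of the laboratory strains C57BL/6J and CAST/EiJ. The effect of CAST/EiJ alleles on mapping to mm10, and so on the level of single genes, was not tested. The labels name total RNA restricted to small sizes and a multiplexed library protocol, and number the animals separately while listing one donor record for both. They define 1 group of 2 biological replicates and no second condition, so no comparison between conditions was made, and every test between libraries compares these 2 libraries only.

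The deposited files hold raw read counts per annotated microRNA gene, in a column that ignores strand and in one column for each strand, per the layout of the files. The assembly was mm10 and the gene annotation GENCODE M21, per the text deposited with the files, and the aligner and counter are not given in the sources used here. All 2202 gene identifiers matched microRNA genes of GENCODE M21, so symbols, coordinates (mm10, counted from 1), host genes and hairpin base composition were taken from that annotation and its genome. Counts refer to hairpin genes, not to the mature arms of each hairpin. The column with the larger gene total in both libraries was taken as the sense column, by a rule set before the data were examined. Reads listed as unmapped, mapping to several places, outside genes or ambiguous name no gene and were left out of library sizes. They took 26.4%, 29.8%, 7.16% and 0% of the reads of replicate 1 and 51.9%, 21.5%, 6.46% and 0% of those of replicate 2. Because reads that map to several places are outside the gene counts, the levels of microRNAs with identical or near-identical copies at several loci are uncertain. In the strand-blind column, genes that overlap a microRNA gene on the opposite strand lose nearly all their reads, so that column served only as an alternative.

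CPM values are the deposited counts of a library scaled to a total of 1000000 over all genes. Means are given with the SD over the 2 libraries (n = 2), and shares of single libraries have exact Clopper-Pearson 95% intervals. A gene with 0 counts may have up to 3 counts, equal to 0.667 CPM in replicate 1 and 1.44 CPM in replicate 2. Intervals and floors cover counting error only, since PCR copies of one molecule cannot be recognised in these counts. Ratios between libraries are replicate 2 over replicate 1 after TMM scaling in edgeR, on the log2 scale, for genes with at least 10 counts in both libraries unless stated. Each such gene was tested with a two-sided exact binomial test of its 2 counts against the ratio of effective library sizes, with Benjamini-Hochberg adjustment at 0.05 over 333 genes. This test takes counting noise as the only error. The biological coefficient of variation came from the edgeR common dispersion, and an edgeR exact test with that dispersion was the alternative. That dispersion was estimated from the difference between the same 2 libraries, so the test ranks genes against the general difference and cannot call many of them. An exact two-sided test of 2 values against 2 cannot go below p = 0.33, so differences between gene lists are set against the SD.

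The 20 lists of microRNA families and cell type markers, the tests, the alternatives and the rule for genes named in the text were fixed before the data were examined. The rule takes the 15 genes with the highest mean CPM, the 5 genes with the largest ratio each way among those past the binomial test, the 3 highest members of each list, the highest and lowest member of the 3 genomic clusters with the most counts, and the 3 highest families of numbered copies. Genes named outside that rule were chosen after their values were seen, and are named as such. Genomic clusters join neighbouring genes of one strand within 10 kb, and the spread of levels within clusters was tested with 10000 permutations of cluster membership across genes, which are not independent replicates. A linear correction for hairpin GC content, and a list of 5 further pancreas-enriched genes written before those genes were looked at, were added after seeing the data.

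Alternatives covered the count minimum (5, 50 or none), library size or DESeq2 median-ratio scaling in place of TMM, the strand-blind column, pseudocounts of 1 and 0.1 CPM, cluster distances of 2 and 50 kb, totals without the highest gene, and leaving out each library. The software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The tests were run on simulated data first. With 200 changed genes drawn from the level of the real libraries, the binomial test between the 2 libraries was run on 335 genes and called 93 of 93 tested genes changed 4-fold, 74 of 94 changed 1.4-fold and 2 of 148 unchanged. These simulated counts held counting noise only and were scaled by the genes known to be unchanged. The rates therefore do not carry over to the real libraries, which were scaled by TMM and differ by more than counting noise. Simulated coefficients of variation of 10%, 40% and 70% over 333 genes were estimated at medians of 10.1%, 40.0% and 66.4%. In 200 draws over 333 genes with no effect, the cluster test, the slope test within clusters and the rank correlation with GC content gave p under 0.05 in 10, 12 and 14 draws.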

Results

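The data are microRNA profiles of the adrenal gland of 2 male B6CASTF1/J mice aged 36 days, with 1 library from each animal. The animals were told apart by their separate numbers in the labels, which list a single donor record for both. Replicate 1 held 12289288 reads, of which 4494857 (36.6%) were assigned to microRNA genes on the sense strand. Replicate 2 held 10323816 reads, of which 2078824 (20.1%) were assigned. With a single group, the profile describes which microRNA genes were counted in the gland and how far the 2 libraries differed. Of 2202 annotated microRNA genes, 749 had at least 1 count in either library and 333 had at least 10 counts in both.

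In the counted profile, let-7 genes held more than any other list, and Mir378a, Mir126a and Mir375 were also among the highest genes. Reads that map to several places, 29.8% and 21.5% of the reads of replicates 1 and 2, are outside this profile. MicroRNAs with copies at several loci may therefore rank too low in it. Mirlet7b, a member of the let-7 family that is high in differentiated tissue, was the highest gene at 132884 ± 68994 CPM (SD, n = 2). It was followed by Mir378a at 74155 ± 28593 CPM, encoded within the gene of the metabolic coactivator Ppargc1b, and by Mirlet7g at 72065 ± 11615 CPM. Mir126a, an endothelial microRNA, reached 69808 ± 7103 CPM, and Mir375, known from endocrine cells such as those of the pancreatic islet, reached 47963 ± 5397 CPM. The SDs leave the order of Mir378a, Mirlet7g and Mir126a, and that of most of the 15 highest genes, unresolved.

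In mm10, Mirlet7b (ENSMUSG00000065564.1) lies on chromosome 15 from 85707319 to 85707403, overlapping an exon of an annotated Lncppara transcript. Mir378a (ENSMUSG00000105200.1) lies on chromosome 18 from 61397835 to 61397900 in an intron of Ppargc1b, and Mirlet7g (ENSMUSG00000065440.1) on chromosome 9 from 106178840 to 106178927 in an intron of Wdr82. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 from 26591357 to 26591429, overlapping an exon of an annotated Egfl7 transcript. Other transcripts of Egfl7 may hold it in an intron. Mir375 (ENSMUSG00000065616.3) lies on chromosome 1 from 74900658 to 74900721 between genes. The next genes were Mirlet7i at 39730 ± 6467 CPM, Mir143 at 35636 ± 13311 CPM, Mir10a of the Hoxb gene cluster at 34139 ± 18451 CPM, Mir23a at 28832 ± 16087 CPM and Mir26b, in an intron of Ctdsp1, at 28352 ± 21895 CPM. Mirlet7d, Mir23b, Mir139 (in an intron of Pde2a), Mir127 and Mir99a completed the 15 highest, from 26210 ± 4623 CPM for Mirlet7d to 15709 ± 3937 CPM for Mir99a. With 1 library alone, Mirlet7b, Mir10a, Mir23a, Mir26b and Mir23b moved by over 1.5 times. Mirlet7b had 84098 and 181670 CPM in replicates 1 and 2, Mir26b 43834 and 12870 CPM, Mir10a 47186 and 21092 CPM, Mir23a 40207 and 17457 CPM and Mir23b 35488 and 15877 CPM.

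The 10 highest genes took 55.8% of the gene counts in replicate 1 (exact Clopper-Pearson 95% interval 55.7 to 55.8) and 58.9% in replicate 2 (58.8 to 58.9), a mean of 57.3% ± 2.18 (SD, n = 2). The 50 highest took 90.2% ± 1.37, and 87 genes had a mean above 1000 CPM. Of the 10 highest genes in each library, 8 were shared. Mir378a and Mir126a overlap another microRNA gene on the opposite strand, and their strand-blind counts fell to 0 and 2.27 CPM, so both rest on the sense column.

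**Figure D1:**
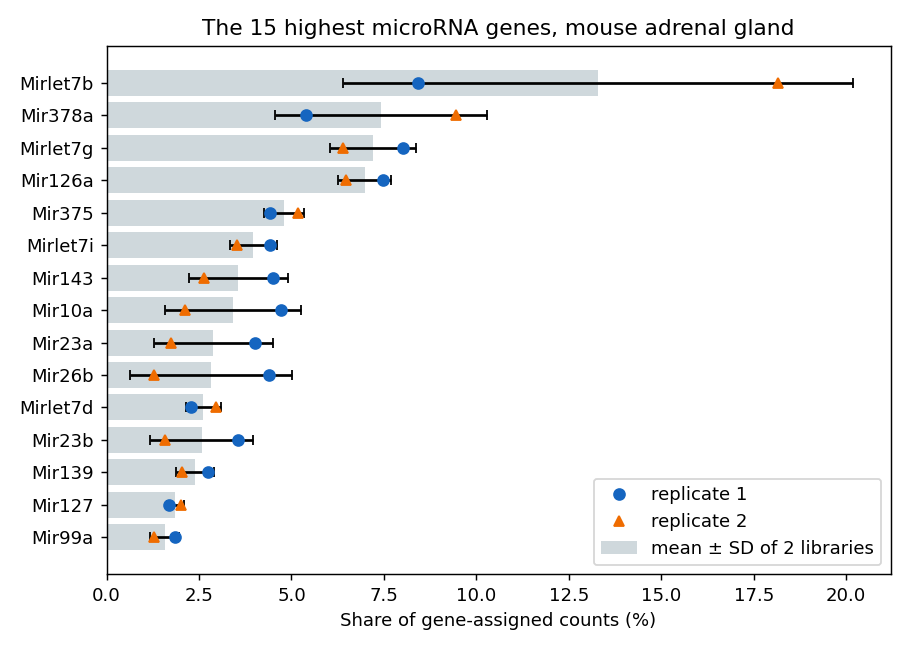
Share of gene-assigned counts (percent, x axis) of the 15 microRNA genes with the highest mean level in the adrenal gland. Bars show the mean and error bars the SD of 2 libraries, with replicate 1 as circles and replicate 2 as triangles; Mirlet7b took 8.41% in replicate 1 and 18.2% in replicate 2.

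Among the families and cell type lists, let-7 held the most counts. The vessel, neuroendocrine, brown adipose, imprinted, and kidney and gut lists each held more than those of neurons, leukocytes, liver or striated muscle. The endothelial, brown adipose, and kidney and gut shares were each nearly all from a single gene. Most of the neuroendocrine share was Mir375, at 4.80% of the gene counts. Most of the smooth muscle and pericyte share was Mir143, at 3.56%. Reads that map to several places are outside all these shares. The 12 let-7 genes took 29.6% ± 6.05 (SD, n = 2) of all gene counts. The endothelial pair Mir126a and Mir126b took 6.98% ± 0.710, nearly all of it Mir126a. The neuroendocrine list took 5.17% ± 0.396, led by Mir375, then Mir7b at 3228 ± 1553 CPM and Mir7-1 at 199 ± 48.2 CPM. The imprinted Dlk1-Dio3 region of chromosome 12, whose microRNAs are expressed from the maternal chromosome, took 5.73% ± 0.109, with 46 of its 55 listed genes at 10 or more counts in both libraries. Its highest members were Mir127 at 18546 ± 2316 CPM, Mir379 at 7445 ± 2394 CPM and Mir411 at 7096 ± 2183 CPM.

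The brown adipose list, chosen for fat around the gland, took 7.58% ± 3.06. Nearly all of it was Mir378a, while Mir193b stood at 1644 ± 1963 CPM and Mir365-2 at 14.9 ± 8.18 CPM. A share that rests on a single gene does not give the amount of fat. The smooth muscle and pericyte list took 3.84% ± 1.16, from Mir143 and Mir145a at 2781 ± 1721 CPM, with 1 count of Mir145b in total. The list of kidney and gut epithelium took 3.44% ± 1.83, nearly all of it Mir10a, whereas Mir204 stood at 132 ± 106 CPM and Mir192 at 49.3 ± 9.91 CPM. The miR-30 family took 3.26% ± 0.112, led by Mir30d at 13558 ± 3913 CPM, Mir30a at 9283 ± 2297 CPM and Mir30e at 7328 ± 2985 CPM. MicroRNAs studied in steroid-producing cells took 2.45% ± 0.941, led by Mir21a at 9707 ± 4411 CPM, Mir125a at 6401 ± 2360 CPM and Mir382 at 2450 ± 78.0 CPM. Mir382 also belongs to the Dlk1-Dio3 list.

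The miR-17/92 clusters, tied to proliferation, took 0.861% ± 0.169, led by Mir93 at 3474 ± 305 CPM, Mir17 at 1956 ± 202 CPM and Mir106b at 994 ± 282 CPM. Leukocyte genes took 0.356% ± 0.0483, with Mir146 at 1744 ± 374 CPM, Mir150 at 919 ± 262 CPM and Mir142 at 493 ± 80.9 CPM. The liver gene Mir122 stood at 2113 ± 1032 CPM. Fibroblast genes took 0.137% ± 0.0219, led by Mir214 at 1326 ± 210 CPM, with Mir199b at 31.6 ± 11.7 CPM and Mir199a-2 at 11.5 ± 1.33 CPM. Mir199a-2 is a numbered copy, and reads shared between copies are outside the counts, so the fibroblast share may be too low. Neuronal genes took 0.0739% ± 0.0406, led by Mir137 at 557 ± 308 CPM, with Mir153 at 76.9 ± 71.3 CPM and Mir138-1 at 46.3 ± 2.55 CPM. Mir124a-1, Mir124a-2 and Mir124a-3, neuronal genes outside the naming rule chosen after their values were seen, had 0 counts in both libraries. Reads shared between such copies are outside the counts, so the neuronal share may be too low. The large repeat-like families miR-297, miR-466, miR-467 and miR-669, with many near-identical copies, took 0.0573% ± 0.00774, from Mir467d, Mir467e and Mir669c at 215 ± 43.9, 139 ± 74.7 and 115 ± 34.6 CPM.

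Pluripotency microRNAs took 0.00659% ± 0.00265, with Mir292, Mir293 and Mir294 at 22.6 ± 15.6, 20.0 ± 11.9 and 11.5 ± 1.45 CPM. Skeletal and heart muscle genes took 0.000887% ± 0.000310, and none of the 10 had 10 counts in both libraries. The 3 highest were Mir499, Mir206 and Mir1b at 3.72 ± 0.859, 3.20 ± 2.96 and 1.48 ± 0.736 CPM. Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2, muscle genes outside the naming rule chosen after their values were seen, had 0 counts in both libraries. Reads shared between such copies are outside the counts, so the muscle share may be too low. The erythroid, miR-200 and pancreas acinar lists differed most between the libraries and are given per library with that comparison. Shares of the neuronal, liver, and kidney and gut lists each moved by over 1.5 times with 1 library alone, to 0.103% and 0.0452%, 0.138% and 0.284%, and 4.73% and 2.14% in replicates 1 and 2.

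**Figure D2:**
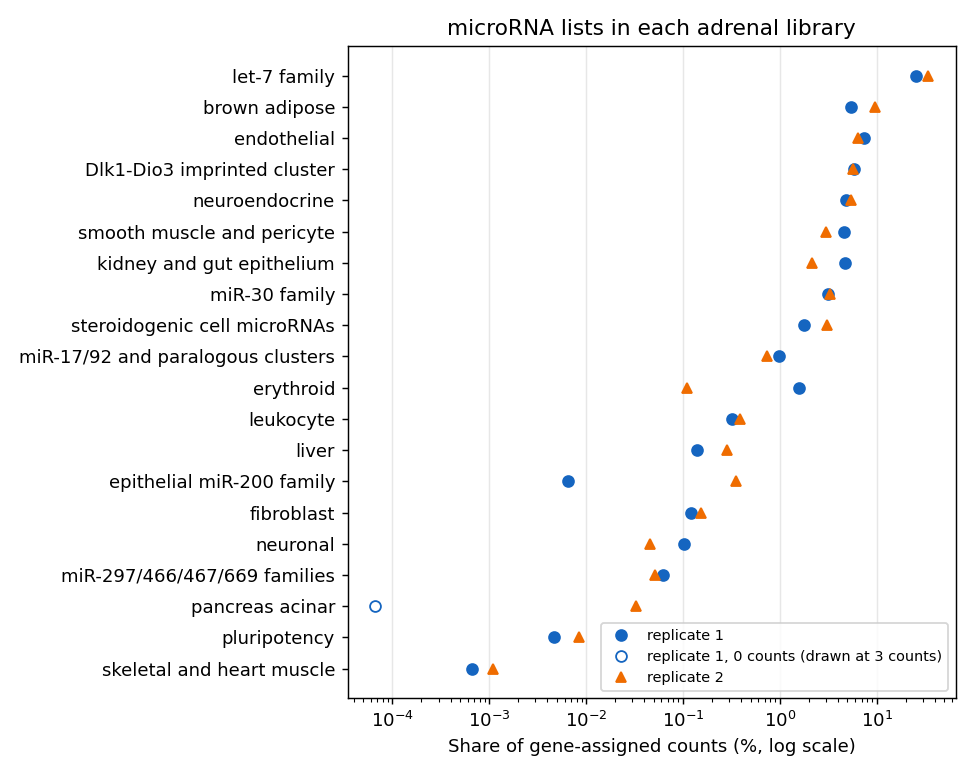
Share of gene-assigned counts (percent, log scale, x axis) of each of 20 microRNA lists in replicate 1 (circles) and replicate 2 (triangles); an open circle marks 0 counts, drawn at 3 counts. The let-7 family is highest at 25.3% and 33.9%, and the erythroid, miR-200 and pancreas acinar lists lie farthest apart between the libraries.

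The erythroid, miR-200 and pancreas acinar lists differed most between the 2 libraries. The erythroid list took 1.58% of counts in replicate 1 (exact 95% interval 1.57 to 1.60) and 0.109% in replicate 2 (0.105 to 0.114), or 16.5-fold more in replicate 1 after TMM scaling. Most of it was Mir451a, which overlaps Mir451b on the opposite strand and had 0 counts in the strand-blind column. The miR-200 family, known from epithelial cells, took 0.00647% (0.00575 to 0.00726) and 0.358% (0.350 to 0.366), or 48.6-fold more in replicate 2. The acinar genes of the pancreas, Mir217, Mir216b and Mir216a, had 0 counts in replicate 1 and 530, 91 and 56 counts in replicate 2. Their sum of 677 counts was at least 429-fold higher than a floor of 3 counts over the list in replicate 1.

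Across the 749 genes with any count, Spearman's rho between the libraries was 0.874, and Pearson's r of log2(CPM + 1) was 0.963. Both are correlations across genes, which are not independent replicates. The biological coefficient of variation was 52.2% over 333 genes, and 242 genes (72.7%) lay within 2-fold of each other while 20 differed by over 4-fold. With 1 library from each animal, that coefficient cannot tell differences between the animals from those of tissue collection, preparation or sequencing. The counts differed far beyond sampling noise (chi-square 506250, 332 degrees of freedom), so the libraries are not 1 library deposited under both names. By the exact binomial test with Benjamini-Hochberg adjustment, 260 of 333 genes differed between the libraries, 129 higher in replicate 1 and 131 higher in replicate 2. The split follows the scaling, and was 112 and 149 with library size alone. The edgeR exact test, whose dispersion was estimated from these same 2 libraries, called 6 genes at an adjusted p under 0.05 and 17 at an unadjusted p under 0.05. It called 3 genes with a count minimum of 50 and 2 in the strand-blind column.

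Among genes with at least 10 counts in both libraries, the largest ratios toward replicate 2 were those of all 5 miR-200 genes. That minimum leaves out the acinar genes, with 0 counts in replicate 1. Mir200c (chromosome 6, 124718322 to 124718390) had 122 and 5683 counts, a log2 ratio of 6.47 with a counting interval of 6.21 to 6.74 and an edgeR exact adjusted p of 0.00110. Mir200a, Mir429, Mir200b and Mir141 had log2 ratios of 4.63, 4.32, 4.27 and 4.14. With edgeR the first 3 of these had an adjusted p of 0.0456 and Mir141 of 0.0532. With the same minimum, the largest ratios toward replicate 1 were those of Mir301, in an intron of Ska2, and of the erythroid pair Mir451a and Mir144. Mir301 (chromosome 11, 87113004 to 87113089) had 5365 and 48 counts, a log2 ratio of -5.88 with a counting interval of -6.32 to -5.47 and an edgeR exact adjusted p of 0.00262. Mir451a had 64554 and 1877 counts, a log2 ratio of -4.18 and an edgeR exact adjusted p of 0.0456. Mir144 had a log2 ratio of -3.42, Mir92-2 of -2.58 and Mir153 of -2.45, with edgeR exact adjusted p of 0.152, 0.720 and 0.732. The third measured erythroid gene, Mir486, had 38.7 and 35.1 CPM and was not past the binomial test (log2 ratio -0.33), but was past it with a correction for hairpin GC content that was added after seeing the data (-0.75).

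**Figure D3:**
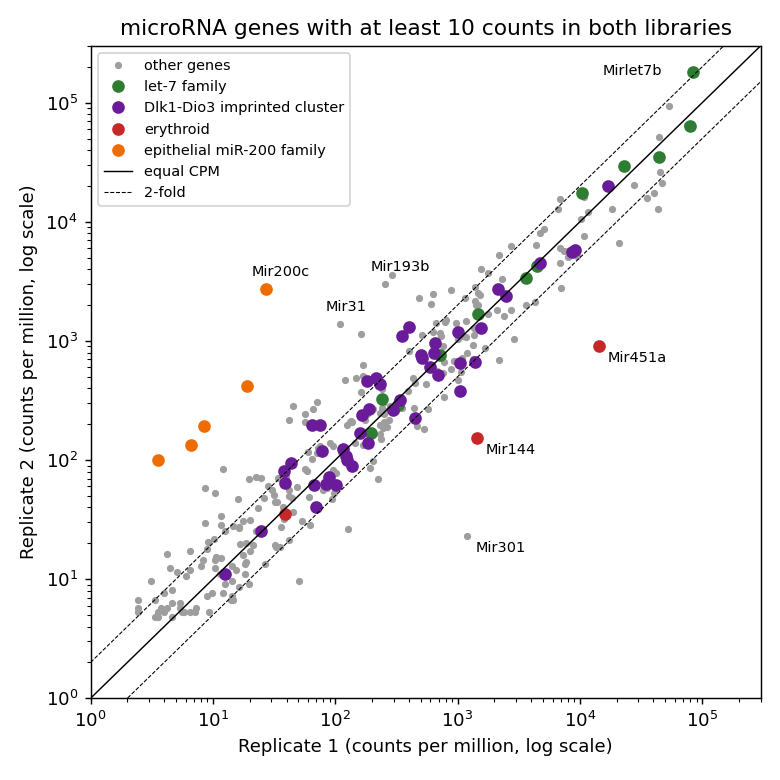
CPM in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, for the 333 genes with at least 10 counts in both libraries. The solid line marks equal CPM and the dashed lines 2-fold; the 5 miR-200 genes (orange) lie above the lines, and Mir451a, Mir144 (red) and Mir301 lie below.

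Of the other 17 lists, the binomial test called genes in both directions in 9, in one direction in 7 and in none for the striated muscle list. All 10 measured genes of the miR-17/92 clusters were higher in replicate 1 after TMM scaling, from Mir92-2 to Mir93 (log2 ratio -0.36) and Mir25 (log2 ratio -0.22), which lies outside the naming rule and was chosen after its value was seen. With library size alone 9 of them were called, and Mir25 stood at 390 and 380 CPM. Of the 5 measured neuronal genes 3 were higher in replicate 1, among them Mir137 (log2 ratio -1.38) and Mir153, and 2 were not past the test (4 and 1 with the GC correction). All 3 measured brown adipose genes were higher in replicate 2, with log2 ratios of 0.62 for Mir378a, 3.38 for Mir193b and 1.00 for Mir365-2, and so was Mir122 (0.85). Of the fibroblast genes 2 were higher in replicate 2, of the pluripotency genes 2, and none of either list was higher in replicate 1. The fibroblast direction did not hold with the GC correction, under which Mir214 turned from 0.14 to -0.10 and no fibroblast gene was called higher in replicate 2.

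Of the 12 let-7 genes, 6 were higher in replicate 1 and 4 in replicate 2, with Mirlet7g at a log2 ratio of -0.52 and Mirlet7b at 0.93. The Dlk1-Dio3 genes split into 21 higher in replicate 1, 19 higher in replicate 2 and 6 not past the test. With library size alone the splits were 6 and 6 for let-7, 18 and 20 for Dlk1-Dio3, 3 and 9 for the steroidogenic list, 2 and 3 for the neuroendocrine list and 1 and 3 for kidney and gut. With the GC correction they were 7 and 4, 23 and 16, 3 and 8, 4 and 2, and 1 and 1 in the same order, and 3 and 1 for leukocyte and 3 and 3 for the repeat-like genes. Mir375 turned from 0.04 to -0.48 and Mir150 from 0.40 to -0.01. Steroidogenic cell microRNAs split into 4 and 7 with 2 not past the test, and included Mir21a (0.78) and Mir132 (1.79), a gene outside the naming rule chosen after its value was seen. The miR-30 genes split into 2 and 4, the neuroendocrine genes into 3 and 3, the kidney and gut genes into 1 and 2, the leukocyte genes into 3 and 2 and the genes of the repeat-like families into 3 and 2. Mir143 was higher in replicate 1 (-0.97) and Mir145a in replicate 2 (1.17). Mir126a (-0.39) and Mir10a (-1.35) were higher in replicate 1, Mir204 (1.68) in replicate 2. Adjusted over the list alone, the counts were 7 and 4 for let-7, 22 and 19 for Dlk1-Dio3 and 4 and 8 for the steroidogenic list, and those of the other lists did not change. None of the calls in these lists, other than Mir200a, Mir200b, Mir200c, Mir429 and Mir451a, passed the edgeR exact test.

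Among genes with at least 10 counts in both libraries, those that lie close together had more similar levels than shuffled genes, although single clusters held large differences. Over 40 clusters, the median absolute difference of log2 CPM between members of one cluster was 2.25, against 3.32 after shuffling (permutation p = 0.0002, 10000 permutations, 706 pairs). Most pairs came from the Dlk1-Dio3 region. Without it the values were 2.30 and 3.45 (permutation p = 0.0025, 109 pairs). Without the count minimum the difference between clustered and shuffled genes was not past 0.05 (permutation p = 0.0966). The cluster with the most counts was Mirlet7b with Mirlet7c-2 on chromosome 15, from 85706603 to 85707403, in which Mirlet7b stood 83.9-fold above Mirlet7c-2 at 1583 ± 157 CPM. The cluster of Mir143 and Mir145a on chromosome 18, from 61647825 to 61649258, had a 12.8-fold difference, of 28.8-fold in replicate 1 and 6.56-fold in replicate 2. In the cluster of Mir23b, Mir27b and Mir24-1 on chromosome 13, from 63300484 to 63301275, Mir23b stood at 25683 ± 13867 CPM and Mir24-1 at 40.7 ± 5.93 CPM. Mirlet7c-2 and Mir24-1 have further copies at other loci, and reads shared between copies are outside their counts.

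The 115 genes with numbered copies in 53 families together took 1.27% ± 0.155 (SD, n = 2) of the gene counts. The highest families were let-7f at 4628 ± 95.7 CPM, let-7c at 2320 ± 192 CPM and Mir16 at 1775 ± 1262 CPM. Reads that map to several places are outside both these counts and the library totals, so the levels of these families are uncertain. Over the 2138 genes with no microRNA gene on the opposite strand, a mean of 99.98% of the counts lay on the strand of the gene. Over all genes the value was 84.4% ± 0.849, but there reads of overlapping genes are counted on both strands. In replicate 1, 336351 sense counts of Mir126a stood beside 336343 opposite-strand counts of Mir126b. Genes with no such partner held 499 of 795859 opposite-strand counts in replicate 1 and 292 of 403174 in replicate 2. The 64 genes with such a partner, Mir126a and Mir378a among them, held 17.7% and 19.4% of the sense counts of replicates 1 and 2.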

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

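The opposite-strand counts of genes without an annotated microRNA partner on that strand enter the report only through the share of counts on the sense strand, and no gene's level rests on them. Mir203, on chromosome 12 from 112130880 to 112130955, had 407 such reads in replicate 1 and 259 in replicate 2, beside 6971 and 2561 reads on its own strand. These counts lie above the limit of 3 counts that a count of 0 allows, and no explanation was tested.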

How the results depend on the processing

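The alternatives with the linear correction for hairpin GC content were chosen after seeing the data, and the others before. The number of genes with 10 counts in both libraries, the share of the 10 highest genes and the count of 260 differing genes stayed within 1.5 times (counts) or 1 SD (the share) under the alternatives run for each, leaving aside the share with 1 library alone, which with 2 libraries always lies within 1 SD, except that the edgeR exact test called 6 genes, as it adds a spread estimated from these same libraries to the error. That count was 5 with library size alone, 6 with median-ratio scaling, 7 without a count minimum, 3 with a minimum of 50 and 2 in the strand-blind column. The genes higher in replicates 1 and 2 by the binomial test were 112 and 149 with library size alone, 133 and 131 with median-ratio scaling, 167 and 132 without a count minimum, and 138 and 111 with GC correction. The GC correction gave 249 differing genes in all and a coefficient of variation of 51.0%. Without a count minimum that coefficient was 60.4%. The correlation between libraries was 0.931 by Spearman over genes with 10 counts, and 0.963 and 0.925 by Pearson with pseudocounts of 1 and 0.1 CPM. Library size alone shifted the median log2 ratio by 0.19 against TMM, and turned the sign of the summed log2 ratio of the miR-30 list from -0.12 to 0.07 and of the neuroendocrine list from -0.03 to 0.16.

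Leaving Mirlet7b out of the total moved let-7 to 18.8%, and by the smaller total miR-30 to 3.78%, neuroendocrine to 5.997%, Dlk1-Dio3 to 6.63%, endothelial to 8.04%, fibroblast to 0.160%, leukocyte to 0.414% and the repeat-like families to 0.0660%. In the strand-blind column, where overlapping genes lose their reads, endothelial fell to 0.000227%, brown adipose to 0.206% and erythroid to 0.0970%, with miR-30 at 3.10%, miR-17/92 at 1.06%, neuroendocrine at 6.33%, Dlk1-Dio3 at 6.63%, fibroblast at 0.168%, the repeat-like families at 0.0703% and numbered copies at 1.47%. That column held 3700022 and 1676236 gene counts in replicates 1 and 2, against 4494857 and 2078824 in the sense column. The smaller totals raised the shares of genes that kept their reads, such as Mir375 (198434 against 198433 counts in replicate 1). Of 67 named genes, 24 moved by more than 1 SD in the strand-blind column and none with TMM. With genes of no counts included, the cluster difference was 0 (permutation p = 0.0966), with 1453 of 2202 genes at 0 in both libraries. The sense share over genes with 10 counts was 93.3%, again with reads of overlapping genes counted on both strands. With 1 library alone, the erythroid share was 0.109% to 1.58%, the miR-200 share 0.00647% to 0.358% and the acinar share 0% to 0.0326%. The causes of the other changes were not tested. The lower count total of replicate 2 sets its floor at 1.44 CPM.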

Other observations

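Apart from Mir301 and Mir30d, the genes in this and the next paragraph lie outside the fixed naming rule and were chosen after their values were seen. They were not tested as groups, and apart from Mir301 none is among the 6 genes called by the edgeR exact test. Of 8 genes of the miR-15/16 seed family, 6 were higher in replicate 1 by the binomial test, beside 129 of all 333 genes tested. They were Mir16-1 (log2 ratio -1.86), Mir322 (-1.85), Mir195a (-1.67), Mir16-2 (-1.45), Mir497 (-0.81) and Mir15a (-0.29). Mir503 did not differ (-0.02, adjusted p = 0.798 in the exact binomial test), and Mir15b, the neighbour of Mir16-2 in an intron of Smc4, was higher in replicate 2 (0.70). In the seed family of Mir301, Mir130a was also higher in replicate 1 (-1.52). Mir130b had 250 and 245 CPM, and its log2 ratio of -0.21 (adjusted p = 0.00790 in the exact binomial test) rests on the TMM scaling. Mir301b had 54 and 4 counts.

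The binomial test called 131 of 333 genes higher in replicate 2, among them the following pairs. Mir107 (2.05) and Mir103-2 (1.60), in introns of the pantothenate kinase genes Pank1 and Pank2, were such a pair, as were Mir132 (1.79) with Mir212 (2.19) and Mir221 (0.96) with Mir222 (1.77). The edgeR exact test gave Mir107 and Mir212 an adjusted p of 0.987 each. Mir30b had a log2 ratio of 3.44 beside 0.41 for Mir30d, and Mir31, a gene with no neighbour named here, had 3.49. By the edgeR exact test Mir30b and Mir31 had an adjusted p of 0.152 each.

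Of the tests in the following paragraphs, that of red blood cell RNA was written after the values it uses had been seen, and the others before, but 2 rules for reading a result were set after it was seen, as stated. The design gives a single group, so no biological explanation by condition was tested.

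The first pattern is the excess of pancreas acinar and miR-200 genes in replicate 2. Replicate 1, with 0 acinar counts, was the library with more gene counts. The median log2 ratio of the 8 genes was 4.87 after GC correction and 4.89 before (residual SD 1.18, counts of 0 set to 3). The linear trend with hairpin GC content therefore does not account for the excess. That trend was too shallow to remove ratios of this size, and other bias by base composition was not tested. Pancreatic RNA in replicate 2 may be a source, but 5 other pancreas-enriched genes had a median log2 ratio of -0.56 (12.4th percentile of 10000 random lists), which met the bound of 0 or less written beforehand against it. The source is still left open, by a rule set only afterwards, because only 1 of the 5 genes was low in replicate 1. Mir148a, Mir182, Mir148b and Mir183 stood at 89.0 to 928 CPM there, and the binomial test called all of them lower in replicate 2. How much pancreatic RNA such levels could hide was not computed. Mir802, the gene that was low in replicate 1, at 1 count, had 344 in replicate 2 (log2 ratio 9.35, counting interval 6.87 to 14.66). Mir6969, in an intron of the pancreatic colipase gene Clps and chosen after its value was seen, had 0 and 89 counts, and whether such RNA came with the tissue or from another library of a multiplexed run was not tested.

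The second pattern is the excess of Mir451a and Mir144 in replicate 1. The ratio nearer to 0 of the pair was -3.16 after GC correction and -3.42 before, beyond the residual SD of 1.18. The linear trend with hairpin GC content therefore does not account for this excess, but it was too shallow to remove such ratios. Other bias by base composition was not tested. More red blood cell RNA in replicate 1 could account for it and stays open. Mir486, the third measured gene, had a log2 ratio of -0.33 (-0.75 with GC correction) and so missed the bound of -1, but it cannot decide the question. Mir486 had only 174 and 73 counts and overlaps Mir3107 on the opposite strand. Mir3107 is also named Mir486b, and reads shared between copies are outside the counts of both genes.

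The third pattern is a trend of the ratio between libraries with hairpin GC content, with a Spearman's rho of 0.26 across 333 genes (permutation p = 0.0001, the smallest that 10000 permutations can give) and a slope of 0.27 per 10 percentage points of GC (SE 0.07), which took up 4.60% of the variance. Base composition bias between the libraries may contribute, but among 146 genes within clusters the slope was 0.12 (SE 0.11, permutation p = 0.253), which neither excludes nor establishes it. A difference in transcription or cell make-up would draw cluster members together after GC correction, and their median absolute difference of 0.74 lay below the shuffled 0.91 (permutation p = 0.047), which met the bound written beforehand. It is still left open, by a rule set after both p-values were seen, because without the Dlk1-Dio3 region the values were 0.80 and 0.94 (permutation p = 0.148). The corrected ratios also no longer hold the linear trend, so their spread within clusters cannot show what caused that trend. The trend therefore cannot be assigned to either.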
